A study of Mus musculus with 6 samples.

How the data were processed

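RNA was taken from frozen, pulverised gastrocnemius muscle with Trizol and sequenced from a standard Illumina library, per the labels' protocols. The authors aligned reads with STAR 2.5.0a to GRCm38.p6, counted fragments with featureCounts 2.0.0 and compared genotypes with DESeq2 (version not given in the sources used here), per the submitters' processing notes. Per the file headers, fragments were counted without regard to strand, and a fragment over several genes was counted for each of them, so genes that share exons share counts. The deposited count table holds raw fragment counts per gene, not normalized. The authors' deposited table holds log2 fold changes, p-values and adjusted p-values for the genes past a p-value and fold limit; 31 adjusted p-values are blank.

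Each count column was assigned to a sample by its name. Gene names and positions came from a GENCODE annotation of GRCm38, which matched 51633 of 51911 gene IDs. Counts were analysed in R 4.3.3. Genes were kept with filterByExpr by genotype, scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test, robust fit, genotype as the sole term), with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is transgenic over wild type, and its SE is the absolute log2 fold change divided by the square root of the F statistic. CPM uses TMM-scaled library sizes. The biological coefficient of variation was 10.7%. A count of 3 equals 0.0804 to 0.134 CPM in these libraries. Ratios for genes with 3 counts or fewer in a library used summed counts, with exact binomial 95% intervals that cover counting error only.

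The comparison, its test, 43 gene lists, the rule for named genes and the alternative settings were set before the data were examined. Of the lists, 42 had at least 3 tested members and entered camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01; camera with an estimated correlation and fry stood beside it. The preset correlation called 11 lists, all lower in the transgenic muscle, while the estimated correlation called 0 (2 at an unadjusted p under 0.05) and fry 20, or 19 without Ppargc1a in its list. The text names Ppargc1a, then genes past the threshold with an assigned symbol, no overlap in CPM between genotypes and a mean of at least 5 CPM in 1 genotype: the 10 largest changes in each direction and the 5 smallest p-values in each direction not already named. A gene that this rule names is not reported here. From each list it may name up to 4 members past the threshold by smallest p. Myh1, Myh4, Myh7, Fbp2, Esrra and Vegfa, and the polyamine, imprinted and family genes of the closing section, were named after their values were seen.

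The alternatives were DESeq2 1.42.0 size factors and its Wald test, with lists then ranked by the Wald statistic, upper-quartile factors, 2 other filters on low counts, limma-voom, a fit without robust estimation, removal of mitochondrially encoded genes, a replicate block and each library left out in turn. On simulated counts for 16362 genes with 200 changed, edgeR recovered 58.2% of those changed 1.5-fold, 83.6% at 2-fold and 100% at 4-fold, with 12 false calls among 173. The simulation changed a far smaller share of genes than was called in the data. It also held no scaling difference between genotypes, so these rates do not carry over to the data. Same-genotype libraries differed by more than sampling noise (chi-square per degree of freedom 10.8 to 26.1), so none was a duplicate.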

Results

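The series profiled gastrocnemius muscle of male mice by bulk RNA sequencing. The transgenic mice carried a construct driving PGC-1alpha3, an isoform of the transcriptional coactivator PGC-1alpha, from the human skeletal actin (HSA) promoter, which is active in skeletal muscle. There were 3 transgenic and 3 wild-type libraries, and the deposited table held a fragment count for 51911 genes in each of the 6. Total counts were 26557948, 26190221 and 32593108 in the transgenic libraries and 26091135, 40846872 and 25532146 in the wild-type libraries. Y-linked Ddx3y had at least 1956 counts and Xist at most 3 counts in every library, the pattern of male tissue. Nothing in the labels says how many animals stand behind each library, so the p-values below measure the spread between these libraries.

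The comparison asked how overexpression of this isoform changes the transcriptome of the muscle. Ppargc1a, the gene the transgene is made from (chromosome 5, 51454250 to 51567726, GRCm38), averaged 2930 ± 422 CPM (counts scaled to library size) in the transgenic libraries and 52.2 ± 1.20 CPM in the wild-type libraries (SD, n = 3 each). Its log2 fold change was 5.81 with a standard error (SE) of 0.12 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.14e-09). Raw Ppargc1a counts were 94358, 73513 and 120862 against 1179, 1809 and 1200, so every label matched its library. These gene-level counts do not separate the transgene from the endogenous gene or one isoform from another.

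Beyond the transgene, genes of glycolysis, fast muscle fibres and calcium handling fell, while the acetylcholine receptor genes Chrna1, Chrnb1 and Chrna9 and the transcription factors Runx1 and Myog rose. Of 16593 genes tested, 8419 (50.7%) passed an adjusted p of 0.05, with 4230 higher and 4189 lower in the transgenic muscle (50.2% higher). Of these, 3979 changed at least 1.5-fold and 1776 at least 2-fold, the latter with 1043 higher and 733 lower. The genotypes did not overlap in CPM for 9889 genes, 59.6% of those tested, where chance gives 10% for 3 libraries against 3. The direction of small changes depended on the scaling: TMM factors averaged 1.15 in transgenic and 0.872 in wild-type libraries, and with library totals alone the median log2 fold change of all genes moved from -0.016 to 0.38, giving 8676 genes higher and 1448 lower (85.7% higher). The 10 most abundant genes held 17.7% to 18.3% of the counts in transgenic libraries and 21.8% to 22.6% in wild-type libraries. Of the 42 gene lists tested, camera called 11 with the preset correlation and 0 with an estimated correlation. Other splits of the 6 libraries into 3 and 3 gave 8 to 19 called lists and 0 changed genes. Each of those splits mixed the genotypes unevenly, so it still carried part of the genotype difference and is no chance baseline. The account of each list below leads with its members' own tests. These are correlated within many lists, and their counts are to be read beside the 50.7% of all tested genes that passed. Changes below are relative to TMM scaling unless stated.

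**Figure D1:**
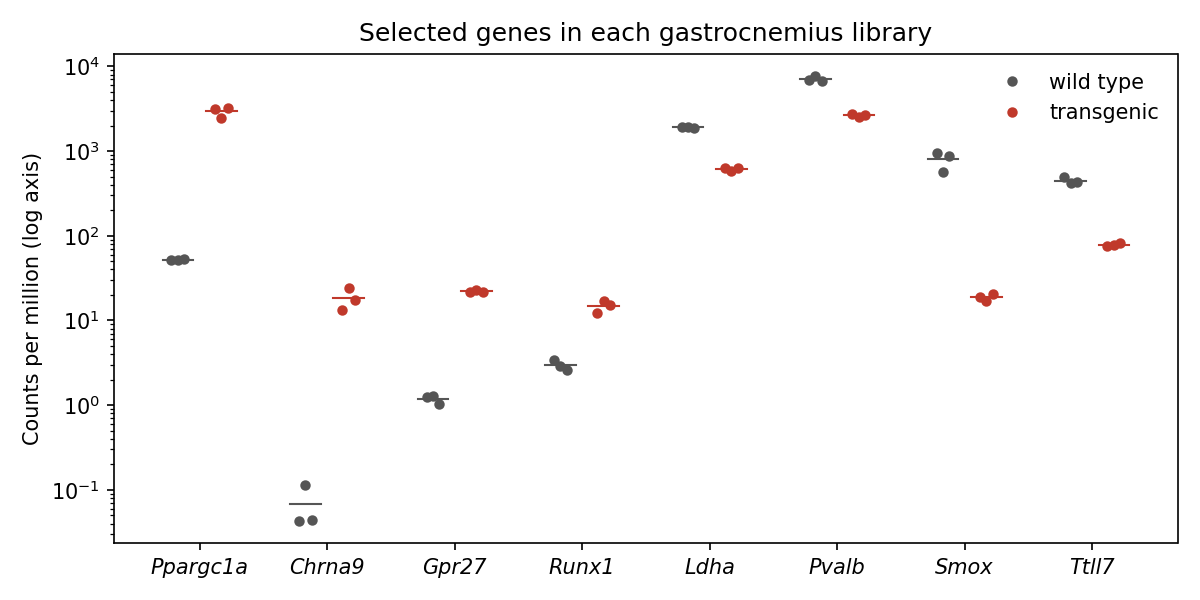
CPM on a log axis of 8 genes in each of the 6 libraries; points are libraries and lines are group means of 3. Ppargc1a, Chrna9, Gpr27 and Runx1 lay higher, and Ldha, Pvalb, Smox and Ttll7 lower, in all 3 transgenic libraries than in any wild-type library.

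Among the genes that rose most, several were close to silent in wild-type muscle. Chrna9, a nicotinic acetylcholine receptor subunit (chromosome 5, 65934921 to 65977326), had 1782 counts over the transgenic libraries and 6 over the wild-type libraries, a ratio of 244 (95% counting interval 112 to 665). Rnf208, which shares 159 exonic bases with Cysrt1, reached a ratio of 86.1 (interval 41.6 to 215), Shisal1 44.3 (31.1 to 65.4) and the keratin Krt18 34.9 (21.4 to 61.5). Snhg11, which shares 133 exonic bases with Gm25187, reached 29.0 (22.4 to 38.2). The fitted log2 fold changes of Chrna9, Rnf208, Krt18 and Snhg11 moved by more than 1.5-fold when 1 wild-type library was left out, up to 8.56 for Chrna9 without replicate 2 and 7.04, 5.79 and 5.81 for the other three without replicate 1. Fbxo2, a ubiquitin ligase subunit, rose by 5.14 (SE 0.18) and Ccdc159, which overlaps Tmem205 by 86 exonic bases, by 5.01 (SE 0.19) on the log2 scale. Igfn1 (5.08, SE 0.77, adjusted p = 0.00657) and Sln, which encodes the calcium pump regulator sarcolipin (4.87, SE 0.77, adjusted p = 0.00714), rose with a wide spread. The Sln value was 5.83 without wild-type replicate 2, and its call ended without both libraries numbered 2 (adjusted p = 0.0628). The Igfn1 call ended without both numbered 1 (adjusted p = 0.102). Removals of both same-numbered libraries were chosen after seeing the data. The replicate block, set before the data were examined, also ended the Igfn1 call (adjusted p = 0.0695). Apart from Ppargc1a and these large changes, the smallest p-values among genes that rose belonged to Gpr27 (4.20, SE 0.11), Sox12 (3.72, SE 0.13), Ppp2r3d (2.16, SE 0.07) and Urod, a haem synthesis enzyme (1.94, SE 0.07), and to Dlg4, which encodes the synaptic scaffold PSD-95, at 44.1 ± 4.22 CPM against 5.17 ± 0.554 CPM (SD, n = 3; adjusted p = 1.66e-08).

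Among the genes that fell most, Fgfbp1, which encodes a fibroblast growth factor carrier, had 730 counts over the wild-type libraries and 2 over the transgenic libraries, a ratio of 445 (95% counting interval 123 to 3678), and both transgenic counts came from replicate 1. Its fitted log2 fold change of -8.47 was -11.0 without transgenic replicate 1 and -7.86 without transgenic replicate 3. The collagen gene Col9a1 had 461 counts against 7, a ratio of 80.2 (interval 38.6 to 201). Intervals cover counting error only. Smox, the spermine oxidase gene, averaged 18.9 ± 1.75 CPM in transgenic and 801 ± 208 CPM in wild-type libraries (SD, n = 3), a log2 fold change of -5.41 (SE 0.26). The log2 fold change was -4.99 (SE 0.39) for Slc15a5, -4.86 (SE 0.24) for Htra4, -4.08 (SE 0.30) for Dach2, -4.03 (SE 0.38) for Odf3l2 and -3.60 (SE 0.33) for Neto2. Ighm, the immunoglobulin mu heavy chain gene of B cells, had a log2 fold change of -4.50 (SE 0.75). It varied from 29.3 to 120 CPM among wild-type libraries, and its call ended without both libraries numbered 1 (adjusted p = 0.118). The smallest p-values among genes that fell belonged to Golm1 (-2.70, SE 0.08), Ttll7 (-2.52, SE 0.08), Slc37a4, the glucose-6-phosphate transporter (-2.01, SE 0.06), Abcb4 (-1.96, SE 0.06) and Sorbs2 (-2.03, SE 0.07). Golm1 shares 1297 exonic bases with Naa35, Sorbs2 1051 with Sorbs2os and Htra4 792 with Gm16933; without strand in the counting, such values are uncertain.

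Glycolysis and fast-fibre transcripts fell together. Of 23 genes of glycolysis and glycogen use, 21 fell and 1 rose, with the same counts adjusted over the list alone. Ldha (-1.63, SE 0.06), Gpi1 (-1.58, SE 0.06), the muscle glycogen phosphorylase gene Pygm (-1.55, SE 0.06) and Pgam2 (-1.51, SE 0.06) had the smallest p-values, and the gluconeogenic Fbp2 was the gene that rose (0.44, SE 0.08). The list median was -1.17 (camera adjusted p = 3.94e-10; adjusted p = 0.383 with an estimated correlation). Of 14 fast-fibre genes, 13 fell and 1 rose, also adjusted over the list alone, with a median of -1.17 (camera adjusted p = 1.26e-06; adjusted p = 0.794 with an estimated correlation). Myoz1 (-1.73, SE 0.07), parvalbumin Pvalb (-1.42, SE 0.07), Tnni2 (-1.27, SE 0.07), Tnnt3 (-1.18, SE 0.07) and the type IIB myosin Myh4 (-1.30, SE 0.09) fell. The type IIX myosin Myh1 rose by 1.07 (SE 0.29, adjusted p = 0.0349), a call lost without transgenic replicate 1 (0.96), transgenic replicate 3 (0.99), wild-type replicate 1 (0.89) or wild-type replicate 2 (1.04). Both list medians stayed below 0 with library totals alone, at -0.77 for glycolysis and -0.78 for fast fibre.

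Of 21 calcium handling genes, 18 fell and 1, Sln, rose, with the same counts adjusted over the list alone (median -0.75, camera adjusted p = 8.63e-07; adjusted p = 0.858 with an estimated correlation). Camk2a (-1.73, SE 0.06) and the junctophilin Jph2 (-1.31, SE 0.08) were among them. Of 20 sarcomere and cytoskeleton genes, 15 fell and 1 rose, or 16 and 1 adjusted over the list alone (median -0.57, camera adjusted p = 2.23e-04; adjusted p = 0.858 with an estimated correlation); with library totals alone 9 were lower and 4 higher (median -0.179). Muscle creatine kinase Ckm (-1.27, SE 0.06) and skeletal actin Acta1 (-0.97, SE 0.07) fell. Of 15 slow-fibre genes, 2 rose and 2 fell: Myl6b (1.95, SE 0.14) and phospholamban Pln (1.54, SE 0.19), which shares 1644 exonic bases with Gm47644, rose, while Myoz2 (-1.24, SE 0.17) and Ankrd2 (-1.05, SE 0.22) fell. The slow-fibre level differed between libraries of 1 genotype, with a mean log2 CPM of 6.19, 6.67 and 5.88 in transgenic and 5.55, 6.53 and 5.29 in wild-type libraries. Slow myosin Myh7 had a log2 fold change of 0.89 (SE 0.83, adjusted p = 0.439), not detectable over this spread with genotype as the sole term. The value was 0.37 without transgenic replicate 2 and 1.86 without wild-type replicate 2.

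Transcripts of the respiratory chain, for which PGC-1alpha is a known coactivator, were lower under TMM scaling. With library totals alone their medians lay just above 0, yet below the median of all genes there (0.38). Of 36 nuclear complex I genes, 26 fell and 2 rose (28 and 2 adjusted over the list alone), including Ndufa8 (-0.91, SE 0.07) and Ndufb8 (-0.71, SE 0.05), while Ndufs8 rose (0.74, SE 0.06). Complex II to IV genes fell in 19 of 25 cases and rose in 0, with the same counts adjusted over the list alone, among them Cycs (-0.87, SE 0.10) and Sdhc (-0.67, SE 0.06). ATP synthase genes fell in 11 of 16 cases and rose in 0 (12 and 0 adjusted over the list alone), among them Atp5c1 (-0.66, SE 0.06) and Atp5b (-0.66, SE 0.07). The medians of these lists were -0.32, -0.37 and -0.33 with TMM and 0.079, 0.03 and 0.061 with library totals alone, where 15, 9 and 3 genes passed as higher and 10, 6 and 5 as lower. Relative to other genes camera also called these lists lower with library totals alone (adjusted p = 0.0170, 0.0122 and 0.0491). That setting moved these lists by 0.396 to 0.397 and the median gene by 0.396. Their place among other genes hardly changed, so these calls are no separate support. The same holds for the tricarboxylic acid cycle list below. With TMM, camera adjusted p-values were 7.77e-05, 5.31e-05 and 0.00123, and each was adjusted p = 0.858 with an estimated correlation. Of 18 tricarboxylic acid cycle genes, 14 fell and 1 rose, also adjusted over the list alone (median -0.44, and -0.044 with library totals alone, where 6 were lower and 5 higher and the list was still called at adjusted p = 0.00431; TMM camera adjusted p = 2.87e-04; adjusted p = 0.858 with an estimated correlation), with Idh3a at -0.75 (SE 0.06) and Dlst at -0.70 (SE 0.05).

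**Figure D2:**
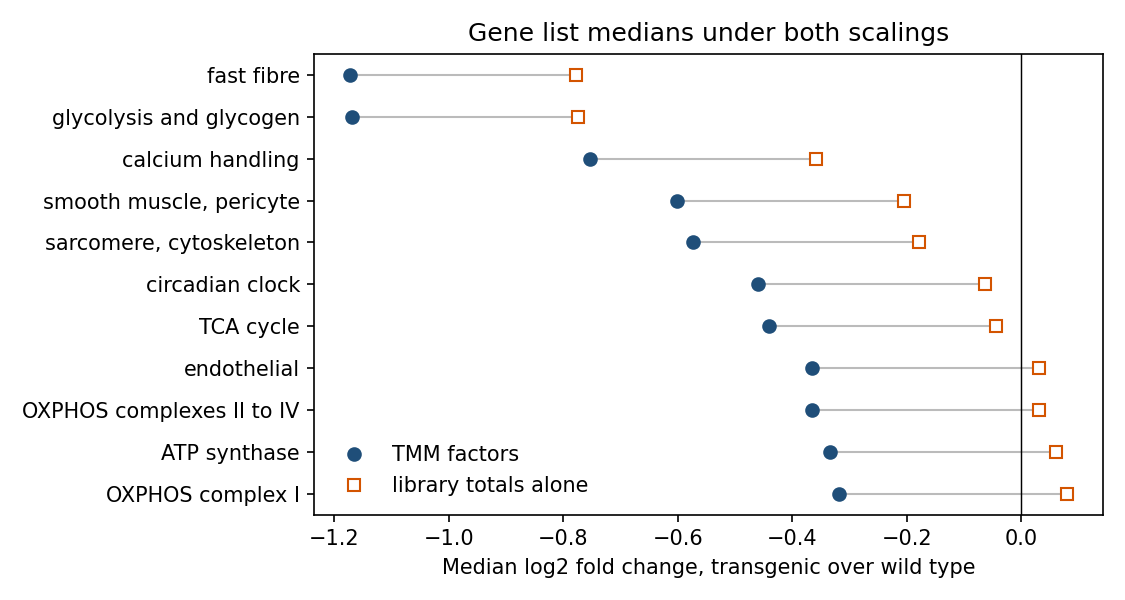
Median log2 fold change, transgenic over wild type, of the 11 gene lists called by camera; filled circles are TMM scaling and open squares are library totals alone. Glycolysis and fast fibre lay below -0.7 under both scalings, while the OXPHOS complex I, OXPHOS complexes II to IV, ATP synthase and endothelial lists crossed 0.

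Other mitochondrial groups were mixed and not called under TMM scaling. Of 10 tested mitochondrially encoded protein genes 3 fell and 2 rose, also adjusted over the list alone (median -0.18, and 0.218 with library totals alone, where 6 were higher and 0 lower), with mt-Co1 at -0.37 (SE 0.06), which turned to 0.028 with library totals alone, and mt-Nd6 at 0.32 (SE 0.08). Mitochondrial transcripts held 11.3% to 11.8% of counts in transgenic and 8.61% to 9.96% in wild-type libraries. Of 23 fatty acid oxidation genes 5 rose and 6 fell (5 and 5 adjusted over the list alone; median -0.045, and 0.353 with library totals alone), with Cpt2 at 0.42 (SE 0.05) and Cpt1b, which shares 2744 exonic bases with Gm44502, at -0.65 (SE 0.07); with library totals alone 20 were higher and 2 lower. Of 78 mitochondrial ribosome genes 36 rose and 20 fell (38 and 20 adjusted over the list alone; camera adjusted p = 0.194), with Mrps14 at 0.72 (SE 0.05) and Mrpl42 at -0.86 (SE 0.05). With library totals alone 59 of these were higher and 7 lower, and the list was called higher (median 0.484, adjusted p = 0.0134), against adjusted p = 0.916 with an estimated correlation under TMM. Of 37 PGC-1 coactivators and partner genes, with the transgene's own Ppargc1a left out after seeing the data, 14 rose and 11 fell (15 and 12 adjusted over the list alone; camera adjusted p = 0.707): the nuclear receptor genes Rxrg (-1.42, SE 0.07), Rxra (-0.88, SE 0.05) and Esrra (-0.69, SE 0.08) fell and Nr1h2 rose (1.08, SE 0.07). Of this list 24 were higher and 5 lower with library totals alone.

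Some neuromuscular and growth genes passed, in both directions, though camera called neither list in the main fit. Of 19 neuromuscular junction and denervation genes 8 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.194, not called). Ranked by the DESeq2 statistic the list was called higher (adjusted p = 0.0150), as with fry (adjusted p = 0.00960), against adjusted p = 0.858 with an estimated correlation. Of its genes 13 were higher and 2 lower with library totals alone. The acetylcholine receptor genes Chrnb1 (1.66, SE 0.07) and Chrna1 (2.29, SE 0.14), Runx1 (2.33, SE 0.15) and Myog (1.66, SE 0.26) rose, and Dok7 fell (-0.79, SE 0.09). Myog is also 1 of 13 tested regeneration and developmental muscle genes, of which 4 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.992, not called; 6 higher and 2 lower with library totals alone). Of 20 growth and myostatin signalling genes 3 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.152, not called; median -0.24, and 0.155 with library totals alone, where 9 were higher and 4 lower). With no filter on low counts camera called the list lower (adjusted p = 0.0339), against adjusted p = 0.911 with an estimated correlation. In it the myostatin gene Mstn (-0.86, SE 0.10) and Gdf11 (-1.28, SE 0.10) fell, while Igf2 (1.96, SE 0.13) and Fstl3 (2.45, SE 0.17) rose, Fstl3 sharing 1157 exonic bases with Prss57 and Igf2 3596 with Gm49394. Of 19 angiogenesis genes 11 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.228, not called; median -0.35, and 0.041 with library totals alone, where 7 were higher and 1 lower). The fry test called it lower (adjusted p = 0.0320), against adjusted p = 0.858 for camera with an estimated correlation. Vegfb was at -0.63 (SE 0.07) and Vegfa at 0.048 (SE 0.09, adjusted p = 0.684), which did not pass under TMM scaling. Either Vegfa or Myh7 passed with library totals alone.

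Clock and vessel genes were lower in the transgenic libraries under TMM scaling. Of 19 circadian clock genes 12 fell and 1 rose, also adjusted over the list alone (median -0.46, camera adjusted p = 0.0190; adjusted p = 0.858 with an estimated correlation), with Cry1 at -1.48 (SE 0.10); with library totals alone 5 were lower and 1 higher (median -0.064). Of 14 endothelial markers 13 fell and 0 rose, also adjusted over the list alone (median -0.37, camera adjusted p = 6.52e-04; adjusted p = 0.858 with an estimated correlation), with Cldn5 at -0.60 (SE 0.09) and Cdh5 at -0.35 (SE 0.05). With library totals alone the endothelial median was 0.03 with 1 marker higher and 0 lower, Cdh5 was 0.048, Cldn5 no longer passed (-0.21, adjusted p = 0.0574) and the list call ended. All 10 smooth muscle and pericyte markers fell, also adjusted over the list alone (median -0.60, camera adjusted p = 0.001; adjusted p = 0.858 with an estimated correlation), led by Abcc9 (-0.82, SE 0.07) and Notch3 (-0.58, SE 0.06); with library totals alone 4 of the 10 were lower (median -0.205). Adipocyte markers differed between libraries of 1 genotype, with a mean log2 CPM of 2.78, 1.23 and 1.65 in transgenic and 4.33, 1.96 and 1.73 in wild-type libraries; 2 of 13 fell, among them Fabp4 (-0.50, SE 0.08), and 0 passed with library totals alone, where Fabp4 was at -0.11 (adjusted p = 0.350). Camera did not call this list with TMM and genotype as the sole term (adjusted p = 0.267). It called the list lower with TMM and the replicate block (median -0.875, adjusted p = 0.0281). With library totals alone it also called the list lower (median -0.835, adjusted p = 0.00450), against adjusted p = 0.916 with an estimated correlation under TMM. Of 15 macrophage markers Cd68 (1.40, SE 0.19) and Lgals3 (1.86, SE 0.30) rose and 0 fell.

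The authors' deposited table listed 3614 genes for the same comparison, 1941 higher and 1673 lower, all with an absolute log2 fold change of at least 0.585 and p of at most 0.0499. Of these, 3355 were tested here, 3325 had the same sign and 3161 (94.2%) passed with that sign. Of the 3979 genes called here at 1.5-fold or more, 3060 were in the authors' deposited table, which gave Ppargc1a a log2 fold change of 5.65. Over the authors' genes tested here the median difference in log2 fold change was 0.006. For genes with the largest changes here the authors' values were smaller in size. They were 5.98 for Chrna9, 3.02 for Igfn1, 2.44 for Sln, 2.08 for Snhg11, -5.37 for Fgfbp1 and -2.87 for Ighm.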

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

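Library totals without TMM factors, the 1.5-fold limit, the removal of both libraries numbered 1 or 2 and that of Ppargc1a from its list were chosen after seeing the data. Changed genes numbered 7563 with DESeq2, 8376 with limma-voom and 7449 to 7888 with 1 library left out (3678 to 4121 higher, 3581 to 3931 lower). They numbered 7027 without both libraries numbered 1, which had the highest adipocyte markers, and 7111 without both numbered 2, with the highest slow-fibre levels. Ppargc1a stayed between 5.74 and 5.95 with 1 library left out. A 2-fold limit left 1776 genes (1043 higher, 733 lower) and a 1.5-fold limit 3979 (2107 and 1872), by construction. Library totals alone gave 8676 higher and 1448 lower; of the 8419 main calls 5678 kept their sign and call and 288 passed with the opposite sign. There the medians of complex I (0.079), complexes II to IV (0.03), ATP synthase (0.061) and endothelial markers (0.03), and mt-Co1 (0.028) and Cdh5 (0.048), turned above 0, by construction of the scaling. Camera called 11 to 12 lists with 1 library left out, 15 with no filter (1 higher), 14 with library totals alone (2 higher), 12 with DESeq2 (1 higher), 0 with an estimated correlation and 20 with fry, which asks another question, or 19 once Ppargc1a was left out of its list (PGC-1 list adjusted p = 0.930). The replicate block gave 8331 changed genes and 12 lists, adding adipocyte markers, and Igfn1 no longer passed (adjusted p = 0.0695). Of the named genes only Myh7 and Vegfa had not passed in the main fit. With this block 1 of them passed, and with library totals alone 1 passed. Same-numbered libraries did not deviate together over all genes (correlations 0.10, -0.09 and -0.21), so the numbers do not pair them there. Agreement with the authors' deposited table was 94.2%, or 92.4% with DESeq2. Of 103 named genes past the threshold, 101 kept their call under every setting chosen before the data were examined, and Igfn1 and Myh1 did not (Myh1 adjusted p = 0.0952 with no filter). Depth limited genes with few counts, such as Fgfbp1.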

Other observations

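The genes here were singled out after their values were seen. Genes of polyamine turnover fell alongside Smox: Amd1, which encodes S-adenosylmethionine decarboxylase (-3.44, SE 0.13 on the log2 scale), and Odc1, which encodes ornithine decarboxylase (-2.82, SE 0.16), were both lower in 3 of 3 transgenic libraries. Imprinted genes rose: H19 by 2.75 (SE 0.11), from 384 ± 30.2 to 2581 ± 397 CPM (SD, n = 3), Zdbf2 by 2.99 (SE 0.17) and Peg10 by 2.46 (SE 0.23). These are single genes, not a tested theme.

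Several lists fixed before the data were examined were not called by camera with the preset correlation and TMM. Of 15 heat shock genes 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.155), with Hspa8 at 0.67 (SE 0.07) and Cryab at 0.62 (SE 0.09). The mean log2 CPM of this list was 6.63 in transgenic replicate 3 against 6.28 and 6.18 in the other transgenic libraries, and that of the immediate early list 4.67 against 3.29 and 3.39. Of 22 antioxidant genes 10 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.126; median -0.18, and 0.211 with library totals alone, where 11 were higher and 4 lower), with Sod2 at -0.85 (SE 0.06) and Txnrd1 at -0.80 (SE 0.07). That list was called lower by fry (adjusted p = 0.00814) and by camera with no filter (adjusted p = 0.0290), against adjusted p = 0.858 with an estimated correlation. Of 76 cytosolic ribosome genes 23 rose and 6 fell, or 20 and 5 adjusted over the list alone (camera adjusted p = 0.0689), with Rps21 at 0.93 (SE 0.07). That list was called higher with no filter, with the stricter filter, without transgenic replicate 2 (adjusted p = 0.0152), without wild-type replicate 2 (adjusted p = 0.00743), without both libraries numbered 2, and with library totals alone (59 higher, 0 lower, adjusted p = 0.00213). It was not called with an estimated correlation (adjusted p = 0.916) or by fry (adjusted p = 0.132). Of 19 interferon response genes 3 rose, led by Ifi27 (1.64, SE 0.07), and of 18 immediate early genes only Ccn1 rose (0.63, SE 0.10); 0 fell in either list, also adjusted over the list alone. With library totals alone 10 and 3 genes of these lists were higher and 0 lower, as were 11 and 0 of the heat shock list. Of 25 atrophy and proteolysis genes 6 rose and 8 fell, also adjusted over the list alone, with Foxo4 at -1.06 (SE 0.05), and fry called the list lower (adjusted p = 0.0253), although its median was 0.004, against adjusted p = 0.916 for camera with an estimated correlation. Of 19 mitochondrial import and quality genes 8 rose, among them Tomm40 (1.05, SE 0.10), and 6 fell, among them Mfn2 (-0.65, SE 0.06), or 9 and 6 adjusted over the list alone. Of 27 splicing regulators 11 rose and 5 fell (13 and 7 adjusted over the list alone), with Mbnl1 at -0.75 (SE 0.07). Of 20 fibroblast and matrix markers 6 fell and Timp1 (1.36, SE 0.34) alone rose, or 1 and 1 adjusted over the list alone. Of 3 lymphocyte markers 1, Cd3e (3.06, SE 0.21), rose and 1 fell, also adjusted over the list alone. With library totals alone these 5 lists had 15, 14, 22, 10 and 1 genes higher and 4, 4, 1, 0 and 1 lower.

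Among the lists not described by name, erythroid markers had the lowest camera adjusted p, 0.0814. Camera called that list lower with no filter (adjusted p = 0.0254) and without wild-type replicate 1 (adjusted p = 0.0243), and fry called it lower (adjusted p = 0.0173), against adjusted p = 0.858 with an estimated correlation. Its median was 0.014 with library totals alone, where 0 of 5 markers passed and camera did not call it (adjusted p = 0.191). Schwann and nerve markers were called lower without transgenic replicate 1 (adjusted p = 0.0119) and with library totals alone (adjusted p = 0.0491, although the median there was 0.088), against adjusted p = 0.916 with an estimated correlation. With TMM, fry also called the unfolded protein, amino acid catabolism and secreted factor lists lower (adjusted p = 0.0346, 0.0379 and 0.0181), against adjusted p = 0.916, 0.916 and 0.858 for camera with an estimated correlation. In these lists 4, 3 and 0 genes rose and 4, 9 and 5 fell, also adjusted over the list alone. With library totals alone 12, 13 and 5 were higher and 3, 5 and 3 lower, and the medians turned to 0.312, 0.245 and 0.135. Of 162 families of like-named genes with at least 10 tested members, camera called 1, Pcdhga (12 of 12 lower, median -0.38, adjusted p = 0.0154; adjusted p = 0.937 with an estimated correlation). The Pcdhga median was 0.02 with library totals alone, where 0 of 12 passed in either direction. All 12 share exonic bases with another gene and each shared fragment was counted for each gene, so they are not 12 separate measurements.

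In the tests below, those on scaling, on fibre share, on genes without overlap and on low genes were chosen after the result was seen. Of the 10 splits of the 6 libraries into 3 and 3, the real one called 8419 genes (1 split with as many) and the highest other called 0, but 10 splits cannot give a share under 0.05. For gene lists under the preset correlation, 7 of the 10 splits called as many as the real 11, and the highest other called 19, with 0 changed genes in that split. Every other split mixed the genotypes unevenly, so it still carried part of the genotype difference, which also adds spread inside its groups. The counts from those splits are therefore no chance baseline, for genes or for lists, and they decide nothing. List statements give their members' own tests. These are correlated within many lists (estimated correlation 0.563 for complex I) and are not separate measurements.

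The first pattern is the lower glycolytic and fast-fibre transcripts. With library totals the median gene moved up by 0.396, and the medians of these lists were still -0.774 and -0.777. The choice between TMM and library totals is therefore argued against as the whole cause. That shift is the same for all genes, so these values answer no wider question about scaling. A lower share of fibres, acting alone, would move the markers of other cell types alike. The satellite cell level minus the smooth muscle level was higher by 0.88 (SE 0.18) on the log2 scale in the transgenic libraries. This pair of lists was chosen after the result was seen. A lower share together with a separate change in either cell type would give the same gap, so a lower share stays open. For the OXPHOS transcripts all 3 lists had medians above 0 with library totals alone, but that setting moved every gene by about as much (0.396 for the median gene), so it decides nothing, and their absolute direction cannot be told apart from the scaling. Genotype, or a difference in preparation that follows genotype, stays open and untested for both.

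The second pattern is adipocyte markers, highest in wild-type replicate 1 and transgenic replicate 1. Fat attached to the dissected piece may be the source in the wild-type library, where 8 of 9 detected genes of a second fat list (88.9%) were highest among wild-type libraries, led by Fasn at 61.5 CPM and Aoc3 at 25.4 CPM. In transgenic replicate 1 it was 7 of 9 (77.8%), under the 80% set in advance, so this stays open for that library. Schwann and nerve markers were also highest in these libraries, at a mean log2 CPM of 3.41 against 1.82 and 2.10 among transgenic and 3.23 against 2.90 and 2.29 among wild-type libraries, which fat alone leaves unaddressed. Fibres also express Fasn, and no biological explanation was tested.

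The third pattern is the 271 genes at least 4-fold higher. No window of 20 Mb held most of them: the fullest held 9 (3.3%). How many of them such a window could hold at most was not worked out. In 1000 random draws the fullest window reached 9 at the 95th percentile, so the observed count does not argue against a cluster. A region that raises only a few genes would not be seen by this test, and genes that fell were not part of it. A passenger region around an insertion therefore stays open as the source of some of these genes. Background reads would raise all low genes, but among tested genes the tenth with the lowest mean had a median log2 fold change of 0.121. Genes removed by the filter were not part of this test. With no filter the median of all genes was 0.107. The transgenic libraries had a count for 27844, 26849 and 25243 genes, and the wild-type libraries for 24335, 24845 and 25287. Background in near-silent genes therefore stays open. Reads shared with overlapping genes cannot be the whole cause, since 170 genes (62.7%) had no annotated exonic overlap. Some overlap was present for 101 of the 271, against 42.7% of all tested genes. For 66 (24.4%, interval 19.4% to 29.9%) the gene with the largest overlap also rose. Partners with a smaller overlap were not checked. For these 66 genes shared reads and a change of their own cannot be told apart without strand. A genotype effect stays among the open explanations.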
